A study of Homo sapiens with 4 samples.

How the data were processed

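m6A was profiled by immunoprecipitation of RNA with an m6A antibody followed by sequencing. Per the labels' protocols, GES-1 cells were left untreated or given 100 µM CDCA for 48 h, RNA freed of ribosomal RNA was made into libraries with an NEBNext Ultra kit, and the libraries were read from both ends on an Illumina instrument. The submitters' processing notes name TopHat2 2.0.13, MACS2 2.1.0 and the build hg19, without saying which step each served. Peaks reached position 249212729 on chromosome 1 and 243186572 on chromosome 2, past the last gene of either chromosome in a GRCh38.p14 gene table, so that table was not used to place peaks.

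The deposited data were a peak list for each immunoprecipitation library, given once as a table and once as plain intervals with identical positions for all 63093 control and 52188 CDCA peaks. Per the file headers, the table holds each peak's start, end, length and summit position, counted from 1. The authors' pileup column is a signal, the height at the summit, per the file headers. The significance of each peak was deposited as −log10 of a p-value and −log10 of a q-value. Per the file headers, fold enrichment is a ratio, taken here as summit height over local background. Peaks were listed separately for each library and not on pooled samples. The input, the filters and the thresholds used to make the lists are not given in the sources used here. The values show that no listed peak had a fold enrichment below 6 and that the lowest −log10 q was 6.37 in the control list and 5.78 in the CDCA list.

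Depth was read from the values, since the lists hold no read counts. Summit heights were whole multiples of 0.862 in the control list and 0.640 in the CDCA list for 100% of peaks, with a tolerance of 0.02 steps. If MACS2 had scaled the immunoprecipitation to the input by its default, the immunoprecipitation libraries held 1.16 and 1.56 times the reads of their inputs. The weakest listed summits then rested on 12 and 15 fragments. The local background was computed from height plus 1 over fold enrichment, minus 1. A Poisson tail with this background gave the listed −log10 p within 2% for 99.9% of 60357 control peaks and 100% of 49835 CDCA peaks with a −log10 p below 200. The lowest background was 0.798 in control and 0.745 in CDCA, and 32.8% (32.4 to 33.2) and 36.7% (36.3 to 37.2) of peaks stood at it. Depth in reads is otherwise unknown.

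Peaks were called shared when they overlapped a peak of the other list by at least 1 bp, and library-specific otherwise. Strand was not used because the lists give none. Chance overlap was estimated by moving every peak of a list by 5 to 20 kb to either side in 100 sets. Moved peaks were not kept within transcribed sequence. Peak numbers missing from a list were counted, and a library-specific peak was said to have a skipped number beside it when the peaks of the other list to its left and right had numbers that were not consecutive. Strong peaks were those with a −log10 q of at least 100, a level chosen after the values had been seen. Peaks were also counted in windows of 1 Mb on chromosomes 1 to 22 and X, by summit. Shares carry exact Clopper-Pearson 95% intervals. The same interval for the CDCA part of all peaks gave that of the ratio of peak numbers. With 1 library per condition, no p-value between conditions was computed, and these intervals leave out biological and technical variation.

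The rule for items to be named was fixed in advance and written for genes: the 10 library-specific genes of each list with the highest significance, the 5 with the most significant peak in each list and the 5 with the largest excess of peaks in each direction. As the lists name no genes and an hg19 annotation was not used here, the rule was carried over to peaks and to 1 Mb windows. Shared genes, peaks per gene, positions in transcripts, sequence motifs, the gene lists fixed in advance and the zinc-finger gene group were not analysed here for the same reason. The longest peaks, library-specific peaks without a skipped number, those with a fold of at least 20 and windows counted at a −log10 q of at least 50 were added after the values had been seen. Alternatives covered the peak thresholds, equal numbers of peaks per list, the definition of overlap, the strength measure and the background level.

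The work used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and bedtools 2.31.1. The overlap, distance and skipped-number steps were tested on 2 simulated lists. The first held 20000 evenly spaced peaks on an artificial chromosome, with lengths drawn from the control list. Against the second list, 100% of these peaks were given the right answer.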

Results

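N6-methyladenosine (m6A) is the most abundant internal modification of messenger RNA. It was mapped in GES-1 cells with and without exposure to chenodeoxycholic acid (CDCA), a primary bile acid. The identity of the cells was not checked here. The series concerned the part played by ALKBH5, an enzyme that removes m6A, in the intestinal change of gastric cells under bile acid, and the comparison asked which m6A sites differed between treated and untreated cells. It comprised 4 samples: an input library and an m6A immunoprecipitation library from untreated cells, and the same pair from cells given CDCA at 100 µM for 48 h. The peak lists of the 2 immunoprecipitation libraries were analysed, and the input libraries were not analysed here as samples of their own. With 1 library per condition there were no replicates, so no test between conditions was possible, and the 95% intervals given are exact Clopper-Pearson intervals that cover counting error only. Fold enrichment, −log10 q and summit height are the authors' own peak values and served to describe, rank and filter peaks within a list. Coordinates are hg19. The lists carry no gene names and an hg19 annotation was not used here, so regions are given by position.

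CDCA-treated cells had fewer listed m6A peaks than control cells. The control list held 63093 peaks covering 18.7 Mb and the CDCA list 52188 peaks covering 15.7 Mb, so the CDCA list had 10905 fewer peaks, or 82.7% (81.8 to 83.7) of the control number. The difference ran across the genome: on each of chromosomes 1 to 22 and X the CDCA list had fewer peaks. Strong peaks, taken as those with a −log10 q of at least 100, numbered 4901 in the control list and 4123 in the CDCA list, which was 84.1% (80.7 to 87.7) of the control number. The shortfall was not even across strength. At a −log10 q of at least 20 the CDCA list held 56.2% of the control number. Below a −log10 p of 20 it held more peaks than the control list (31060 against 27409). Peak length was alike in both lists. The median length was 228 bp in control and 224 bp in CDCA, the mean length 297 bp and 300.7 bp, and 33.3% and 33.2% of peaks had the minimum length of 200 bp. Median fold enrichment was 9.67 in the control list (quartiles 7.49 and 13.5) and 8.63 in the CDCA list (7.07 and 11.4), and median −log10 q was 19.9 and 14.4. The lists were made separately, each against its own background, so these medians show no change in methylation.

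The strongest m6A sites were common to control and CDCA-treated cells, and most other peaks were listed in 1 library only. Of the control peaks, 11466 (18.2%, 17.9 to 18.5) overlapped a CDCA peak by at least 1 bp, and 51627 were control-only. Of the CDCA peaks, 11584 (22.2%, 21.8 to 22.6) overlapped a control peak, and 40604 were CDCA-only. When the peaks of a list were moved by 5 to 20 kb in 100 sets, a mean of 3.07% of control peaks (range 2.93 to 3.19) and 3.71% of CDCA peaks (3.52 to 3.90) overlapped the other list. Sharing rose with strength. Among the weakest 10% of peaks by −log10 q, 5.63% of control peaks (5.07 to 6.22) and 5.31% of CDCA peaks (4.71 to 5.95) were shared. In the 10% just below the strongest 10%, 28.8% of control peaks (27.7 to 30.0) and 46.3% of CDCA peaks (45.0 to 47.7) were shared. Among the strongest 10%, 80.8% of control peaks (79.8 to 81.7) and 87.6% of CDCA peaks (86.6 to 88.4) were shared. At a −log10 q of at least 500, 1000 of 1012 control peaks (98.8%, 97.9 to 99.4) and 838 of 854 CDCA peaks (98.1%, 97.0 to 98.9) had a partner in the other list. A peak that was not listed may have lain under the authors' thresholds, so control-only and CDCA-only mean listed in that library alone.

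**Figure D1:**
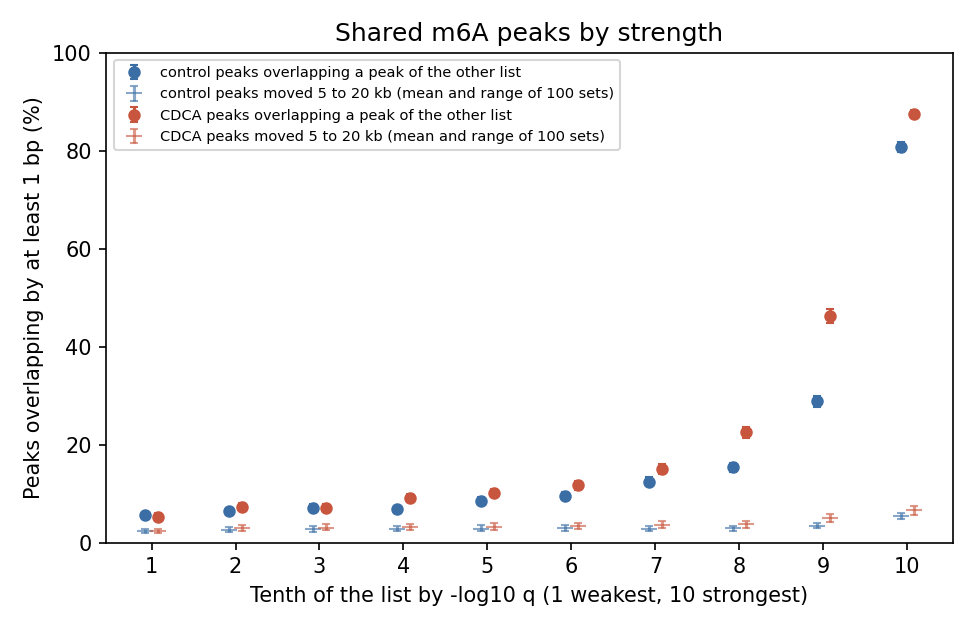
Share of m6A peaks (%) that overlapped a peak of the other list by at least 1 bp, for each 10% of the control list (blue) and the CDCA list (red) ordered by −log10 q, with exact 95% intervals; the pale crosses and bars are the mean and range of 100 sets of peaks moved by 5 to 20 kb. The share rises from 5.63% to 80.8% in the control list and from 5.31% to 87.6% in the CDCA list, while moved peaks stay between a mean of 2.35% and 6.61%.

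Over all peaks of a list, shared peaks had longer median length, higher median fold enrichment and higher local background than library-specific peaks. Shared control peaks had a median length of 390 bp, fold enrichment of 12.9 and −log10 q of 60.5, against 218 bp, 9.19 and 17.6 for control-only peaks. In the CDCA list the medians were 381 bp, 11.7 and 47.2 for shared peaks and 213 bp, 8.22 and 12.7 for CDCA-only peaks. Peaks over 1000 bp were shared in 94.1% of 1131 control cases (92.5 to 95.4) and 94.9% of 960 CDCA cases (93.3 to 96.2). Peaks of the minimum length of 200 bp were shared in 5.92% of 20986 control cases (5.61 to 6.25) and 6.79% of 17329 CDCA cases (6.42 to 7.18). The local background that the peak caller had set under each summit was recovered from height and fold enrichment. Its median was 4 for shared and 1.14 for control-only peaks, and 3.40 for shared and 0.900 for CDCA-only peaks. Where the background was at least 10, 74.5% of 4139 control peaks (73.1 to 75.8) and 80.2% of 3534 CDCA peaks (78.9 to 81.6) were shared. Where it stood at the lowest level of its list, 6.79% of 20684 control peaks (6.45 to 7.14) and 7.78% of 19178 CDCA peaks (7.41 to 8.17) were shared. Within bands of −log10 q, either the order of fold or that of background changed, but not both. At a −log10 q of 50 to 100, control-only peaks had a median fold of 20.7 against 15.1 for shared peaks, and CDCA-only peaks 14.5 against 14.4. At 100 or more, a band with no upper limit, library-specific peaks kept the lower fold. Their median background was the higher one there, 14 against 12.9 in control and 22.2 against 13 in CDCA.

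The most significant m6A sites of both cell populations lay at the same positions. The top peak of each list was on chromosome 1, at 94639344 to 94640374 in control (fold enrichment 54.6, −log10 q 21048) and at 94639354 to 94640401 in CDCA (44.2 and 16732). The second was on chromosome 17, at 48166452 to 48167837 in control (89.4 and 14867), with a CDCA peak at 48166448 to 48167838 (99.8 and 12561). The third was on chromosome 11, at 122928177 to 122928575 in control (15.3 and 11821) and 122928176 to 122928585 in CDCA (19.2 and 11248). The control list continued with chromosome 19 at 3958454 to 3959573 (133 and 11298; CDCA partner 141 and 8117) and chromosome 6 at 83075197 to 83076605, which had the highest fold enrichment of each list (429 in control, and 264 for its CDCA partner at 83075268 to 83076797). The CDCA list continued with chromosome 6 at 132269793 to 132270617 (15.8 and 10583; control partner 13.3 and 8088) and chromosome 8 at 143784427 to 143784967 (66.1 and 9956; control partner 45.3 and 7816). All 5 leading peaks of each list had a partner, and 3 of them were among the 5 leading peaks of both lists. The longest peak of each list was also the same site, on chromosome 11, spanning 5607 bp in control (62287379 to 62292985) and 5502 bp in CDCA (62287482 to 62292983). A site of 4195 bp on chromosome 8 (144993468 to 144997662) measured 4177 bp in the CDCA list (144993461 to 144997637). The control peak at 105414418 to 105419164 on chromosome 14, 4747 bp long, met 3 separate CDCA peaks. Conversely, the CDCA peak at 137709961 to 137713750 on chromosome 9, 3790 bp long, met 2 separate control peaks. The longest peaks were picked out after their values had been seen.

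Among peaks listed in control cells alone, the 10 with the highest −log10 q had a fold between 6.13 and 19.9, and 5 of them were below 10. The leading control-only peak lay on chromosome 9 at 136216335 to 136217472 (fold 6.68, −log10 q 2673), and the nearest CDCA peak was 5319 bp away. The next was a peak of 1560 bp on chromosome 18 at 12325080 to 12326639, with the highest fold of the 10 (19.9, −log10 q 1915). Others lay on chromosome 1 at 86048463 to 86049005 (6.13 and 1430), chromosome 8 at 11702138 to 11702634 (6.44 and 1089) and chromosome 7 at 150932137 to 150932795 (11.4 and 842). The remaining 5 were on chromosome 20 at 3765928 to 3767010, chromosome 7 at 2413982 to 2414232, chromosome 21 at 47423471 to 47423942 and 28216866 to 28217733, and chromosome 3 at 12881475 to 12881708. Their −log10 q ran from 808 down to 538. In total, 608 strong control peaks had no CDCA partner, and their median fold of 13.5 compares with 22.3 for the 4293 strong control peaks that were shared.

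Among peaks listed in CDCA-treated cells alone, the 10 with the highest −log10 q had a fold between 6.02 and 16.1, and 8 of them were below 10. The leading CDCA-only peak lay on chromosome 18 at 346216 to 347432 (fold 8.10, −log10 q 1427), 473 bp from the nearest control peak. It was followed by chromosome 1 at 93300239 to 93300666 (9.34 and 1311), chromosome 3 at 184052575 to 184052908 (9.38 and 1103), chromosome 2 at 10924086 to 10924400 (7.20 and 1026) and chromosome 20 at 32677274 to 32677769 (7.79 and 1023). A CDCA-only peak on chromosome 11 at 62293190 to 62294090 (7.14 and 878) began 205 bp beyond the longest control peak. Broad CDCA-only peaks were found on chromosome 1 at 59247351 to 59249447, with 2097 bp and the highest fold of the 10 (16.1), and on chromosome 2 at 235949503 to 235952036, with 2534 bp and a fold of 7.13. The other two were on chromosome 6 at 26250589 to 26250891 (6.02 and 991) and chromosome 9 at 127998619 to 127999032 (10.8 and 778). In total, 361 strong CDCA peaks had no control partner, with a median fold of 10.1 against 21.5 for the 3762 strong CDCA peaks that were shared.

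All 20 of these named peaks lay where the other list had left out peak numbers. Every peak carries a running number, and both lists skip numbers: the control list held 63093 of 110153 (57.3%) and the CDCA list 52188 of 100129 (52.1%). No listed peak had a fold enrichment below 6. Of the 607 strong control-only peaks that had CDCA peaks on both sides, 559 (92.1%, 89.7 to 94.1) lay between CDCA peaks whose numbers were not consecutive, against 80.4% (76.8 to 83.4) after moving them by 5 to 20 kb. Among the 361 strong CDCA-only peaks, 352 (97.5%, 95.3 to 98.9) had a skipped number beside them in the control list, against 78.2% (73.4 to 81.7) after moving. That left 48 strong control-only and 9 strong CDCA-only peaks at which the other list had no skipped number. A skipped number gives no position, so it shows only that a peak was numbered somewhere between the listed neighbours.

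**Figure D2:**
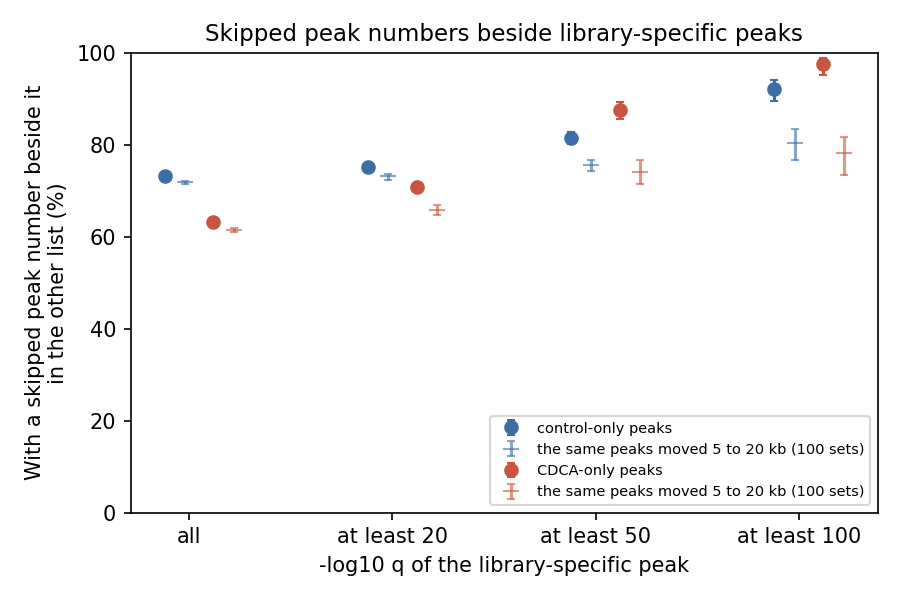
Share of library-specific peaks (%) with at least 1 skipped peak number beside them in the other list, by minimum −log10 q, for control-only (blue) and CDCA-only (red) peaks with exact 95% intervals; the pale crosses and bars are the mean and range of 100 sets of the same peaks moved by 5 to 20 kb. At a −log10 q of at least 100 the share is 92.1% for control-only and 97.5% for CDCA-only peaks, above the moved sets.

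Chromosome 19, which is gene-dense and known for its clusters of zinc-finger genes, had the highest share of common peaks. There 29.9% of 1851 control peaks (27.8 to 32.1) and 34.7% of 1620 CDCA peaks (32.4 to 37.1) were shared. The lowest shares in control were on chromosomes 18 (15.1%, 13.2 to 17.1) and X (15.1%, 13.6 to 16.8), and the lowest in CDCA was on X (17.6%, 15.8 to 19.5). Strong peaks were 245 of the 1851 control peaks on chromosome 19, against 85 of 1344 on 18 and 108 of 1988 on X. In CDCA they were 191 of 1620 on chromosome 19 and 82 of 1689 on X. Sharing rose with strength, and strength was not held equal between chromosomes. The CDCA list came closest to the control number on chromosome 21, with 650 against 700 peaks (92.9%), and fell furthest short on chromosome 3, with 3786 against 4876 (77.6%). Of 2824 windows of 1 Mb with a peak in either list, 1875 held more control peaks, 732 held more CDCA peaks and 217 held equal numbers. The window richest in peaks, chromosome 19 at 58 to 59 Mb, had 104 control and 102 CDCA peaks, of which 44 and 43 were shared.

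Single windows departed from the genome-wide ratio in both directions. Chromosome 3 at 185 to 186 Mb held 66 control peaks and 18 CDCA peaks, the largest control excess, and with a −log10 q of at least 50 it held 11 and 3. Control peaks also outnumbered CDCA peaks on chromosome 5 at 37 to 38 Mb (79 and 42), chromosome 16 at 67 to 68 Mb (82 and 49), chromosome 3 at 104 to 105 Mb (71 and 39) and chromosome 17 at 78 to 79 Mb (74 and 43). CDCA peaks outnumbered control peaks most on chromosome 21 at 46 to 47 Mb (59 and 42) and chromosome 18 at 21 to 22 Mb (49 and 32). With a −log10 q of at least 50, the chromosome 21 window held 16 CDCA and 18 control peaks, so the excess did not hold at that level. In the chromosome 18 window, 1 peak of each list was shared and 1 of each list had a −log10 q of at least 50. Further CDCA excesses lay on chromosome 10 at 32 to 33 Mb (47 and 31), chromosome 4 at 140 to 141 Mb (51 and 37) and chromosome 11 at 107 to 108 Mb (31 and 17). With a −log10 q of at least 50, they held 6 and 4, 3 and 5, and 3 and 4. These windows are the extremes of 2824 and were not tested.

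**Figure D3:**
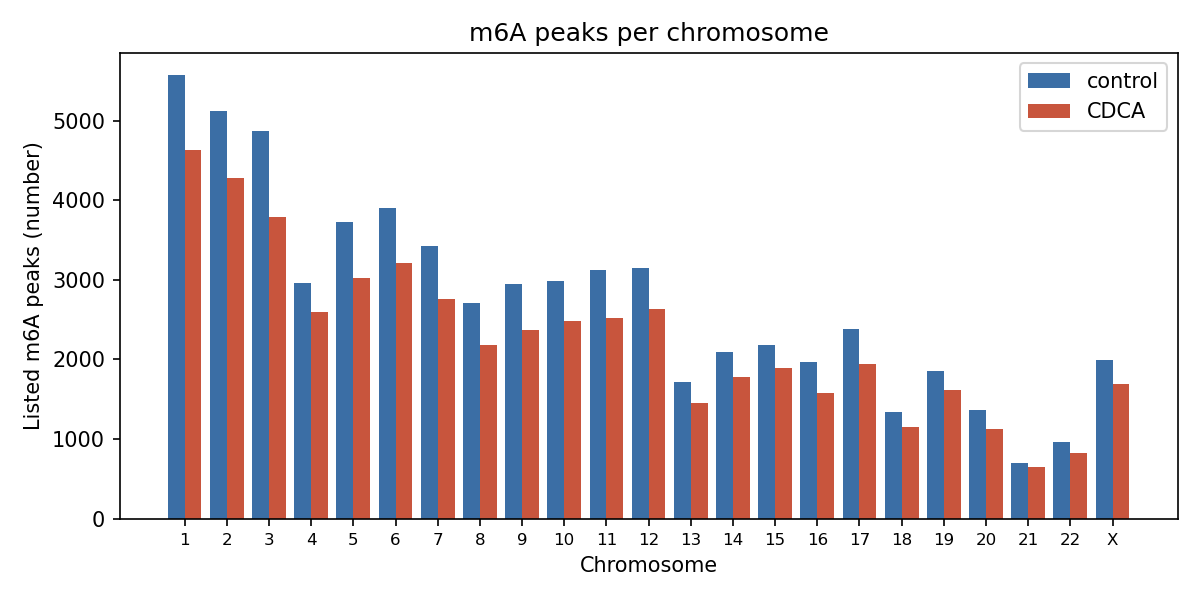
Number of listed m6A peaks on chromosomes 1 to 22 and X in the control library (blue bars) and the CDCA library (red bars), 1 library per condition, so there are no error bars. The CDCA bar is lower on each chromosome, from 77.6% of the control number on chromosome 3 to 92.9% on chromosome 21.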

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

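All tests in this part were chosen after the results they bear on had been seen.

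The control list skips 47060 peak numbers and the CDCA list 47941, a sign of called peaks outside every comparison of listed peaks, and this bears on strong peaks listed in 1 library only. Of these, 92.1% of control-only and 97.5% of CDCA-only peaks had a skipped number beside them in the other list, more than after moving the peaks (at most 83.4% and 81.7%). Many partners of strong peaks may thus have been called and then left out for low fold enrichment. Over all library-specific peaks the excess was small: 73.2% of control-only and 63.2% of CDCA-only peaks, against means of 71.9% and 61.6% after moving. A partner called and left out is excluded for the 48 control-only and 9 CDCA-only strong peaks without a skipped number. A listed partner placed slightly elsewhere is excluded as the general cause, since 3.29% and 4.71% of the strong library-specific peaks had a peak of the other list within 200 bp. Skipped numbers give no position, so a displaced partner that was left out could not be seen. A change of whole transcripts stays open: strong library-specific peaks had a shared peak within 10 kb 0.875 (control) and 0.894 (CDCA) times as often as strong shared peaks, and a neighbour can belong to another transcript. An effect of CDCA on these sites also stays open and was not tested.

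Few peaks were shared between the lists, although the overlap exceeded that of moved peaks. Even among the weakest 10% of peaks, 5.63% of control and 5.31% of CDCA peaks were shared, against at most 2.77% and 2.82% after moving. Moved peaks were not kept within transcribed sequence, so chance overlap within the same transcripts is not excluded. Peaks well above the thresholds of their own list were often unshared too. Of peaks with a −log10 q of at least 20 and a fold of at least 10, 29.5% of 24487 control peaks (29.0 to 30.1) and 49.0% of 13298 CDCA peaks (48.2 to 49.9) overlapped any peak of the other list, which leaves 17257 and 6777 library-specific. The shares depended on the level: at a −log10 q of at least 50 they were 65.1% and 80.9%. Strength was taken from a peak's own list, so partners just under the thresholds of the other list are not excluded. Weak peaks may have contributed, since the share rose to 80.8% and 87.6% in the strongest 10% of the lists. A part played by CDCA treatment cannot be told apart from library-to-library variation, because there was 1 library per condition.

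The CDCA list held fewer peaks than the control list. The gap lay among peaks with a −log10 p of at least 20, 35684 in control and 21128 in CDCA, while below 20 the CDCA list had more peaks (31060 against 27409). Multiplying control heights and backgrounds by 0.934, the ratio of the lowest backgrounds, did not close that gap. With the Poisson tail computed again, 33343 control peaks stayed at 20 or more, and 9547 against 7315 CDCA peaks at 50 and 4747 against 4236 at 100. This changed the scaled heights only. No fragments were drawn again, so the depth of the immunoprecipitation libraries was not tested as a cause. Loss of weak peaks alone is excluded, since the number of strong CDCA peaks was 84.1% (80.7 to 87.7) of the control number. The efficiency of the immunoprecipitation cannot be told apart from an effect of CDCA, because there was 1 library per condition.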

How the results depend on the processing

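The settings at a fold of at least 10, at a −log10 q of at least 20 or 100, without skipped numbers and with rescaled background were chosen after the data had been seen, and the others before the data were examined. Percentages counted as moved outside their counting interval, and counts and ratios of medians beyond 1.5 times. By that measure 43 alternative values moved, 0 reversed and 43 did neither, but 28 of these could not have changed: the planned thresholds (−log10 q of at least 5, fold of at least 4) removed no peak, and stricter overlap cannot give a library-specific peak a partner. Within 200 bp, the 20 named library-specific peaks still had none.

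Shared percentages (control, then CDCA) were 12.99 and 15.7 with 50% reciprocal overlap, 16.9 and 20.6 with the summit inside the other peak, and 20.5 and 24.998 within 200 bp. With the top 5000 peaks of each list, 71.4% and 72.0% were shared and 1432 and 1401 were library-specific. At a fold of at least 10 there were 29651 and 18415 peaks (CDCA 62.1% of control), with 24309 and 13041 library-specific and 18.0% and 29.2% shared. At a −log10 q of at least 20 there were 31399 and 17653 peaks (56.2%), with 24.5% and 43.8% shared and 23717 and 9919 library-specific. At 100 or more there were 4901 and 4123 (84.1%), with 66.3% and 79.0% shared and 1650 and 866 library-specific. Against all peaks of the other list, the level of 20 gave 29.5% and 48.2% shared with 22141 and 9153 library-specific, and the level of 100 gave 87.6% and 91.2% with 608 and 361. Library-specific peaks without a skipped number were 13848 and 14935. The rescaled control background put CDCA at 84.2% of control over all peaks, where rescaling hardly moves the fold. Measured by fold instead of −log10 q, shared peaks exceeded library-specific ones 1.41 and 1.42 times (3.43 and 3.73 by −log10 q, 4.50 and 5.06 with reciprocal overlap). The cause of these shifts was not tested.

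Alternatives for genes, peaks per gene, transcript positions, motifs, gene lists, zinc-finger genes and strand were not run. No paired analysis was possible because there was 1 library per condition. Depth is known only through summit height, and peaks resting on few fragments limit what the weak part of each list can show.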

Other observations

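The tests of peaks without a skipped number, of peaks with a fold of at least 20, of windows at a −log10 q of at least 50 and of neighbouring peaks were chosen after the data had been seen.

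Strong library-specific peaks at which the other list had no skipped number mostly had a high fold over a low background. At a given −log10 q, a low background goes with a high fold by calculation. The 48 strong control-only peaks of this kind had a median fold of 39.9 and a median length of 306.5 bp, and 21 of them (43.8%, 29.5 to 58.8) stood at the lowest background, against 88 of 4293 strong shared control peaks (2.05%, 1.65 to 2.52). The most significant was on chromosome 4 at 186527890 to 186528326 (fold 85.8, −log10 q 283, background 0.800), with the nearest CDCA peak 14861 bp away. It was followed by chromosome 17 at 33768881 to 33769251 (44.7 and 237), chromosome 12 at 83526009 to 83526352 (67.2 and 207) and chromosome 11 at 69310426 to 69310688 (62.8 and 192). The 9 strong CDCA-only peaks of this kind had a median fold of 38.2, and 3 stood at the lowest background. They included chromosome 7 at 148394872 to 148395260 (38.2 and 152), chromosome 9 at 47165612 to 47166293 (46.9 and 141), chromosome 15 at 64592582 to 64592894 (48.6 and 134) and chromosome 11 at 66240543 to 66241567 (30.2 and 133). An exception was chromosome 8 at 29927211 to 29927553, with a fold of 6.25 over a background of 40.0. At a −log10 q of 50 to 100 there were 576 such control-only peaks with a median fold of 23.6, against 15.1 for shared control peaks of that strength, and 157 such CDCA-only peaks.

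If no partner had been called and left out, 118.8 strong control-only and 78.8 strong CDCA-only peaks would have lacked a skipped number, from the moved peaks. With 48 and 9 found, an estimated 40.4% of strong control-only peaks (34.0 to 47.5 over the range of the moved sets) and 11.4% of strong CDCA-only peaks (9.38 to 13.6) had no numbered partner. At a −log10 q of at least 50 the estimates were 75.6% (72.3 to 79.2) and 48.3% (43.9 to 53.4), so they depended on the level chosen. The estimate assumes that skipped numbers lie as densely around these peaks as around the moved positions.

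Other library-specific peaks with high fold did have skipped numbers beside them. On chromosome 19 at 58264686 to 58265673, inside the window richest in peaks, a control-only peak had a fold of 72.4 and a −log10 q of 325. Control-only peaks on chromosome 6 at 56471470 to 56472626 (28.6 and 461) and chromosome 3 at 98557532 to 98558330 (21.3 and 299.7) were the other two most significant with a fold of at least 20. In the CDCA list they were on chromosome 12 at 30954709 to 30955009 (40.1 and 243), chromosome 9 at 115449488 to 115449975 (20.7 and 211) and chromosome 1 at 233119006 to 233119749 (20.3 and 205).

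Counting peaks with a −log10 q of at least 50 alone gave other windows than counting all peaks. Chromosome 17 at 42 to 43 Mb had 20 such control peaks and 9 CDCA peaks, chromosome 6 at 56 to 57 Mb had 26 and 16, and chromosome 10 at 75 to 76 Mb had 20 and 11. Chromosome 8 at 146 to 147 Mb had 6 control and 12 CDCA peaks, of which 5 and 11 were shared. Chromosome 19 at 58 to 59 Mb had 30 and 31. A shared peak lay within 10 kb of 39.1% of the 608 strong control-only peaks (35.2 to 43.2) and 44.7% of the strong shared control peaks (43.2 to 46.2). For CDCA the shares were 40.2% of 361 (35.1 to 45.4) and 44.9% (43.4 to 46.6).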
